A study of Mus musculus with 12 samples.

How the data were processed

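Messenger RNA was measured by bulk RNA sequencing in 12 mouse libraries, 3 in each of 4 groups. Per the labels, all-lymphoid progenitors were sorted from C57BL/6 bone marrow, transduced with a retrovirus carrying GFP alone or TOX with GFP, and cultured for 4 days on irradiated OP9 stroma with stem cell factor, Flt3 ligand and IL-7 at 30 ng/ml. Cells that were Mac1-negative and GFP-positive were then sorted. The labels give the genotype as Tcf7YFP/+ for the wild-type groups and as Tcf7YFP+ Nfil3-KO for the knockout groups, and they do not say which part of Nfil3 was deleted. Libraries were made from polyA RNA by a SMART-Seq2 type of amplification with a transposase step, which does not mark the strand, so that reads of a gene and of an overlapping or antisense partner cannot be told apart. All 12 libraries carry batch 4. The labels do not say whether replicates came from separate animals or separate cultures, so every p-value below measures the spread between these samples only.

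The deposited count table holds expected counts per Ensembl gene, estimated reads with decimals, for 56980 genes; 9.10% of its values are not whole numbers. Per the submitters' processing notes, RSEM 1.3.2, STAR 2.7.10b, limma and edgeR 3.36.0 were used with genome build mm39, and the notes give no role or order for them. A second deposited table holds normalized signal values for 16640 gene symbols and the mean signal per group. The sorted values of its columns coincide within 0.131% (median spread), as quantile normalization gives, and 100% of its 200 highest values are multiples of 0.01 divided by 18 (tolerance 0.001 of that unit), as a mean over 18 columns would give; the other columns of that normalization are not analysed here. It also gives the authors' log2 fold changes of TOX over GFP within each genotype, and the authors' p-values and adjusted p-values of the same comparisons, for 10219 of these genes.

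Symbols were matched to the Ensembl IDs through a name table of GENCODE release M21, which is on another build than mm39, so no coordinates are given. A symbol was found for 52073 IDs and none for 4907, of which 409 were among the genes tested. The same release gave transcript lengths and GC content. Reads that near-identical gene copies share were divided by the authors' estimation, so single members of families such as the H2 genes are less certain than single-copy genes.

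Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 15114 genes holding at least 99.9% of the counts of each library, and libraries were scaled with TMM. The fit had one mean per group over all 12 libraries, with no covariate and no replicate block. Quasi-likelihood tests gave 7 contrasts: TOX against GFP in each genotype, knockout against wild type under each construct, the interaction, and both effects averaged over the other factor. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. All tests were two-sided, and the first group named is the numerator of every fold change. Values per gene are CPM (counts relative to the TMM-scaled library total), mean ± SD over 3 libraries, and log2 fold changes ± SE. Where every library of a group was at 0, the fold is given as a bound, with the group set to 3 counts in each library, a mean of 0.0710 CPM. Where a group held 1 to 3 counts in total, CPM are given without a fold. The SD is the spread over the libraries of a group, and the SE includes the spread between libraries estimated by the fit. Floors cover counting error only, and the reads carry no molecular identifiers.

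The 20 lists of genes were tested with camera (limma 3.58.1) on the same counts and design, with a preset correlation between genes of 0.01 and adjustment over the 20 lists, and again with an estimated correlation and with fry. The lists were ILC precursor, ILC2, ILC3 and LTi, NK and ILC1, T lineage, B lineage, lymphoid progenitor, myeloid, dendritic cell, mast and basophil, erythroid and megakaryocyte, stroma, cell cycle, interferon response, exhaustion-associated, immediate early and heat shock, p53 targets, circadian PAR bZIP, integrins and homing, and mitochondrial transcripts. They hold 463 distinct genes, of which 379 were tested and 46 belong to more than 1 list; Tox and Nfil3 are in none. For members of a list, p-values were also adjusted over the list alone.

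The groups, contrasts, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names Tox and Nfil3. It adds, per contrast, up to 7 higher and 7 lower genes past the threshold with a mean of at least 5 CPM and groups that do not overlap. It then adds up to 4 members of each list by smallest p-value, or up to 6 where the list passed. A gene under this rule is not reported here. For averaged effects it asks for counts only, and genes named there were chosen after their values were seen.

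Alternatives were other scalings (RLE, upper quartile), no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, a fit of only the groups compared, the replicate number as a block, and leaving out each of the 12 libraries in turn. Added after the data were seen were a fit without the 2 libraries with the fewest detected genes, which leaves GFP_KO with 1 library and takes the spread from the other groups, the number of detected genes as a covariate, the slope of each library against transcript length as a covariate, and a score per library and list, mean log2(CPM + 1), with an exact permutation of labels within strata over 400 relabellings. The steps were tested on simulated data with 200 changed genes among 15114. For TOX in wild-type cells, 7 of 67 genes changed 2-fold were called, 30 of 67 changed 4-fold and 38 of 66 changed 16-fold, with 3 false among 78 calls. For the averaged knockout effect, 16 of 67, 41 of 67 and 43 of 66 were called, with 1 false among 101 calls. In 1 run with no change simulated, edgeR called 0 genes, camera 0 lists and DESeq2 41 genes. The simulated genes were drawn independently around 1 mean profile. These runs therefore hold no correlation within lists and no structure among libraries, and false calls under either were not tested. In 5 simulations with the ILC precursor list lowered 2-fold, camera called that list in 5, and 4 calls of other lists were made over the 5.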

Results

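Gene expression was measured in lymphoid progenitors of the mouse after 4 days of culture with a retrovirus that carried either GFP alone or the transcription factor TOX. The cells were wild type or lacked NFIL3, a transcription factor that innate lymphoid cells (ILCs) need to develop. The design asks what forced TOX does with and without NFIL3. The 4 groups of 3 libraries were wild-type cells with GFP (GFP_WT), knockout cells with GFP (GFP_KO), wild-type cells with TOX (TOX_WT) and knockout cells with TOX (TOX_KO). The total was 41.05 M to 42.98 M counts per library. Between 14317 and 17564 genes had a count, with the fewest in GFP_KO replicates 1 (14317) and 2 (14446). Libraries of one group correlated at a Spearman rho of 0.918 to 0.969 across genes, and libraries of different groups at 0.901 to 0.960. The biological coefficient of variation over the tested genes was 81.3%. The first principal component held 16.9% of the variance and set GFP_KO replicates 1 (-144) and 2 (-123) apart from the other libraries.

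Nfil3 followed the labels in every library, and Tox did within each genotype. Nfil3 (ENSMUSG00000056749) had 1693, 2134 and 3374 counts in GFP_WT and 1964, 1965 and 2855 in TOX_WT, against 72, 70 and 32 in GFP_KO and 73, 91 and 106 in TOX_KO. Its mean was 57.0 ± 17.3 CPM in GFP_WT, 1.35 ± 0.471 in GFP_KO, 53.3 ± 12.7 in TOX_WT and 2.10 ± 0.365 in TOX_KO. Nfil3 fell in the knockout by 5.39 ± 0.39 on the log2 scale under GFP (edgeR adjusted p = 0.000277) and by 4.66 ± 0.38 under TOX (edgeR adjusted p = 0.000891). Tox (ENSMUSG00000041272), whose counts pool transcripts of the vector and of the cell's own gene, had 112, 330 and 1494 counts in GFP_WT and 939, 497 and 317 in GFP_KO. With the TOX vector it had 3134, 2027 and 3151 counts in TOX_WT and 1309, 1665 and 1318 in TOX_KO. The means were 14.9 ± 16.6, 13.6 ± 7.03, 65.1 ± 15.0 and 33.6 ± 5.99 CPM in the same order. The log2 fold change of Tox was 2.13 ± 0.71 in wild-type cells (edgeR adjusted p = 0.858) and 1.3 ± 0.69 in knockout cells (edgeR adjusted p = 0.930), neither past the threshold; without GFP_WT replicate 3, the control library with 1494 counts, the first was 3.55. In both genotypes every TOX library lay above every GFP library. Across genotypes, GFP_WT replicate 3 (33.8 CPM) lay above TOX_KO replicates 1 (30.4) and 3 (29.8). By chance 3 libraries lie apart from 3 others, in either direction, in 10% of comparisons. An exact permutation of the construct labels within genotypes gave p = 0.005 for Tox, the smallest that 400 relabellings can give, and p = 0.39 for Nfil3. The same test of the genotype labels within constructs gave an exact p = 0.005 for Nfil3 and 0.6 for Tox.

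**Figure D1:**
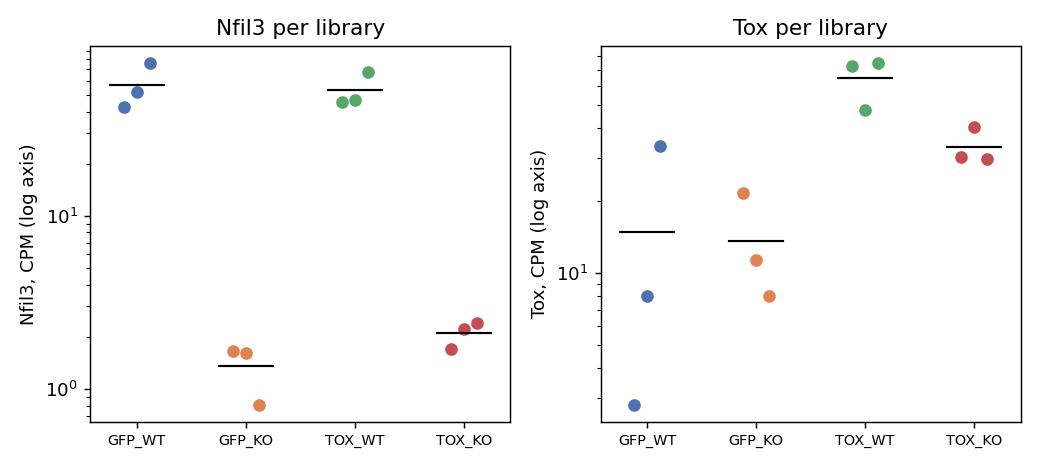
CPM of Nfil3 and Tox in each of the 12 libraries on a log axis, with points for libraries and a line at the group mean. Nfil3 is at most 2.10 CPM on average in the knockout groups against at least 53.3 CPM in the wild-type groups, and Tox is higher in each TOX library than in each GFP library of the same genotype.

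The comparison of GFP_KO with GFP_WT asks what the loss of NFIL3 changes in control cells. Genes of ILC precursors, of natural killer (NK) cells and ILC1, and of mast cells and basophils lay lower in the knockout, and genes of the B lineage lay higher. The B lineage list passed with the preset correlation and by fry (fry adjusted p = 0.0430) but not with an estimated correlation. The ILC precursor list holds transcription factors and receptors of the bone marrow precursors from which ILCs arise. Of its 24 measured members 18 were lower, with a median log2 fold change of -1.28 (camera adjusted p = 2.4e-10; adjusted p = 0.0375 with an estimated correlation). Adjusted over the list alone 6 members were lower, and adjusted over all genes 0. Id2, a repressor of B and T cell programmes that marks all ILCs, had 22.2 ± 14.1 CPM in the knockout and 107 ± 39.4 in wild type (log2 fold change -2.27 ± 0.45, adjusted p = 0.0036 over the list alone). Tcf7, which encodes TCF-1 and carries the YFP reporter, had 0.0727 ± 0.0467 against 9.06 ± 7.48 CPM, and the labels write the reporter genotype differently for the knockout. Gata3, needed for ILC2 and T cells, had 2.08 ± 1.86 against 18.4 ± 8.26 CPM, Ikzf2 0.0659 ± 0.0779 against 4.68 ± 1.81, and Itga4 26.7 ± 6.81 against 53.4 ± 20.4. Il1rl1, the IL-33 receptor, was at 0 in every knockout library and at least 53.4-fold lower, and it also belongs to the mast and basophil list.

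The NK and ILC1 list was lower in 24 of 25 members under GFP, with a median of -2.60 (camera adjusted p = 1.32e-10; adjusted p = 0.0375 with an estimated correlation). Adjusted over the list alone, 4 members were lower. Nkg7, a protein of cytotoxic granules, had 72.3 ± 5.88 CPM in the knockout against 122 ± 26.1. Gzmb, which also belongs to the mast and basophil list, was at 0 in the knockout and at least 40.2-fold lower. Xcl1 had 0.0169 ± 0.0292 against 5.93 ± 4.75 CPM and Cd160 0.0506 ± 0.0877 against 6.30 ± 8.47, both highest in GFP_WT replicate 1 (11.4 and 16.01 CPM). In the other GFP_WT libraries Cd160 had 2.46 and 0.429 CPM. The mast and basophil list was lower with a median of -6.93, or -5.53 with bounds in place of fitted folds, in 14 of 16 members (camera adjusted p = 2.05e-12; adjusted p = 0.0375 with an estimated correlation), and 11 were lower adjusted over the list alone. Cpa3, a mast cell protease, had 0.360 ± 0.0911 CPM against 109 ± 84.4, and Hdc, which makes histamine, 0.655 ± 0.639 against 63.6 ± 39.8. The myeloid list, from cells that had passed a Mac1-negative sort, was lower with a median of -0.74 (camera adjusted p = 1.27e-07; adjusted p = 0.0432 with an estimated correlation). Mpo, Fcgr3 and Spi1 were lower and Cd33 higher adjusted over the list alone. The B lineage list was higher with a median of 1.17 (camera adjusted p = 2e-07; adjusted p = 0.0593 with an estimated correlation), and 4 of its 27 members were higher adjusted over the list alone. The B lineage kinase Blk had 37.3 ± 4.06 CPM in the knockout against 4.02 ± 1.71 in wild type (log2 fold change 3.21 ± 0.50, adjusted p = 0.00115 over the list alone). Igll1, of the surrogate light chain, had 22.7 ± 20.05 against 0.0151 ± 0.0261 CPM, Cd79a 12.9 ± 15.7 against 0.0840 ± 0.106 (with 0, 30.4 and 8.28 CPM in the knockout libraries), and Vpreb3, at 0 in wild type, was at least 32.0-fold higher.

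A further 7 lists passed under GFP with the preset but not with the estimated correlation, and of these only ILC2 also passed by fry (fry adjusted p = 0.0384). Lower were ILC2 (adjusted p = 0.00446; adjusted p = 0.0836 with an estimated correlation) and, with values in the same order, ILC3 and LTi (0.0167 and 0.238), dendritic cell (0.0102 and 0.405), interferon response (6.91e-05 and 0.225), integrins and homing (9.1e-06 and 0.188) and mitochondrial transcripts (0.0198 and 0.490). Cell cycle genes were higher (0.00446 and 0.211), with 25 of 30 members up and a median of 0.14 over all 30. The interferon-induced Oasl2 was lower adjusted over the list alone (log2 fold change -2.48 ± 0.58, adjusted p = 0.0316), as were Gata3 and Il1rl1 in the ILC2 list. The remaining 8 lists did not pass: lymphoid progenitor (0.0882), T lineage (0.180), erythroid and megakaryocyte (0.0540), stroma (0.206), exhaustion-associated (0.0935), immediate early and heat shock (0.0955), p53 targets (0.278) and circadian PAR bZIP (0.278, its mean negative and its median and test positive). ILC3 and LTi was not past the threshold without GFP_WT replicate 1 (0.0884) or 3 (0.0651) or GFP_KO replicate 1 (0.116) or 3 (0.0794), dendritic cell without GFP_WT replicate 1 (0.0884) or 3 (0.168) or GFP_KO replicate 2 (0.152), and cell cycle without GFP_KO replicate 1 (0.103). Mitochondrial transcripts missed it without GFP_WT replicate 1 (0.833) or 2 (0.108) or GFP_KO replicate 1 (0.371). Without both GFP_KO replicates 1 and 2, the libraries set apart on the first component, GFP_KO is 1 library and the spread comes from the other groups. In that fit 5 of these 7 lists did not pass. Dendritic cell was then at 0.707 with a median of -0.08 instead of -0.38, and cell cycle at 0.846 with a median of -0.01 and 13 of 30 members up. The medians of ILC2 (0.146) and of ILC3 and LTi (0.0750) were no smaller in size, at -0.60 instead of -0.51 and -1.14 instead of -0.97, and that of mitochondrial transcripts (0.976) was -0.02 instead of -0.25.

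Gene by gene, edgeR called 1 of 15114 genes between GFP_KO and GFP_WT, Nfil3 itself, while 1122 genes had an unadjusted p under 0.05 and 755.7 would by chance. DESeq2 called 200 genes and limma-voom 0. Leaving out a library raised the edgeR count to 8 without GFP_WT replicate 3, 36 without GFP_KO replicate 3, and 2 without TOX_WT replicate 2 or TOX_KO replicate 3. The 755.7 genes at an unadjusted p under 0.05 by chance hold for every contrast below. The counts for the knockout under TOX (594) and the interaction (688) lie under that number, and the others above it, TOX in the knockout (775) the closest.

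The comparison of TOX_KO with TOX_WT asks whether cells with forced TOX still depend on NFIL3. The groups also differed in their mean level of Tox, 33.6 ± 5.99 CPM in TOX_KO and 65.1 ± 15.0 in TOX_WT, which this comparison cannot separate from the genotype. Genes of ILC precursors and of NK cells and ILC1 again lay lower without NFIL3. The ILC precursor list was lower in 20 of 24 members with a median of -0.99 (camera adjusted p = 1.09e-12; adjusted p = 0.0282 with an estimated correlation; fry adjusted p = 0.0786). Adjusted over the list alone 7 members were lower, and over all genes 0. Id2 had 46.4 ± 11.4 CPM in TOX_KO and 145 ± 29.1 in TOX_WT (log2 fold change -1.64 ± 0.44, adjusted p = 0.0254 over the list alone). Rora, a nuclear receptor of ILC2, had 1.47 ± 1.23 against 24.3 ± 16.9 CPM, Gata3 5.17 ± 3.54 against 37.6 ± 21.4, Tcf7 0.548 ± 0.623 against 24.3 ± 15.0, and Zbtb16, which encodes the ILC precursor factor PLZF, 0.0155 ± 0.0268 against 7.0 ± 5.60. The NK and ILC1 list was lower in 21 of 25 members with a median of -1.19 (camera adjusted p = 1.02e-13; adjusted p = 0.0139 with an estimated correlation), and 6 were lower adjusted over the list alone. Xcl1 and Cd160 were at 0 in every TOX_KO library, at least 130-fold and at least 117-fold lower. Nkg7 had 47.5 ± 4.65 against 91.0 ± 8.66 CPM (log2 fold change -0.94 ± 0.18), the chemokine Ccl5 0.377 ± 0.471 against 17.9 ± 5.14, and Il2rb, a receptor subunit for IL-2 and IL-15, 1.74 ± 0.584 against 27.8 ± 17.1.

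Under TOX 10 further lists passed with the preset correlation, none of them with the estimated one. B lineage was higher (adjusted p = 2.95e-05; adjusted p = 0.168 with an estimated correlation), with Dntt, the terminal transferase of early lymphocytes, at 272 ± 139 against 77.7 ± 36.4 CPM (adjusted p = 0.0189 over the list alone). Cell cycle was higher (0.0339 and 0.358). Lower were ILC2 (0.00273 and 0.108), ILC3 and LTi (0.00444 and 0.213), dendritic cell (0.00191 and 0.396), mast and basophil (0.000133 and 0.193), interferon response (1.5e-06 and 0.193), exhaustion-associated (0.00518 and 0.213), integrins and homing (1.64e-05 and 0.203) and mitochondrial transcripts (0.000634 and 0.408). In the dendritic cell list the class II genes H2-Ab1 (6.12 ± 1.80 against 133 ± 104 CPM), H2-Eb1 (1.61 ± 0.917 against 86.4 ± 65.5) and Cd74 were lower adjusted over the list alone, and the mast and basophil list, with a median of -1.41, had 0 such members. The other 8 lists did not pass, with adjusted p of 0.0504 for stroma, 0.0677 for myeloid, 0.106 for T lineage and for erythroid and megakaryocyte, 0.392 for lymphoid progenitor and for immediate early and heat shock, 0.403 for circadian PAR bZIP and 0.524 for p53 targets; in lymphoid progenitor, stroma and circadian PAR bZIP the median, mean and test differed in sign. Without TOX_WT replicate 3 the lists ILC3 and LTi (0.237), dendritic cell (0.253), cell cycle (0.594) and mitochondrial transcripts (0.273) were not past the threshold, nor was ILC2 without TOX_KO replicate 3 (0.0546) or cell cycle without TOX_KO replicate 1 (0.0688) or 3 (0.0620). Between single genes of TOX_KO and TOX_WT, edgeR called Nfil3 alone, with 594 genes at an unadjusted p under 0.05; DESeq2 called 88 and limma-voom 0, and edgeR called 2 without GFP_KO replicate 1.

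Averaged over both constructs, 6 libraries of each genotype were compared. edgeR called 12 genes, 11 lower and 1 higher in the knockout, with 1052 at an unadjusted p under 0.05; DESeq2 called 249 and limma-voom 7. Among the lower genes, named after their values were seen, were Nfil3 (log2 fold change -5.03 ± 0.27, edgeR adjusted p = 1.07e-05), Anxa2 (-1.98 ± 0.24, adjusted p = 0.0291), Tcf7, Cpa3, Nkg7, Xcl1, Kif21b, H2-Q7, H2-Ab1 and Gm42031, the last 8 with an adjusted p of 0.0465. Lrmp, an endoplasmic reticulum protein of lymphoid cells, was higher (0.85 ± 0.13, adjusted p = 0.0465). Nfil3 stayed past the threshold without each of the 12 libraries in turn, while the count changed by more than 1.5 times for 11 of them. It was 1 without GFP_WT replicate 1, any TOX_WT replicate, or TOX_KO replicate 1 or 3, and 2 without GFP_WT replicate 2, GFP_KO replicate 2 or TOX_KO replicate 2. It was 7 without GFP_KO replicate 1 and 36 without GFP_KO replicate 3.

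Of the lists, 14 passed for the averaged knockout effect, and 6 of them also with an estimated correlation. ILC precursor (adjusted p = 1.74e-19; adjusted p = 0.00896 with an estimated correlation), ILC2 (4.13e-05 and 0.0182), NK and ILC1 (3.2e-20 and 0.00572), mast and basophil (1.9e-15 and 0.0174) and myeloid (5.16e-07 and 0.0380) were lower, and B lineage (1.69e-10 and 0.0292) was higher. Adjusted over the list alone, 12 members of ILC precursor, 11 of NK and ILC1 and 10 of mast and basophil were lower, and 9 of B lineage higher. With a score per library, the mean log2(CPM + 1) of the members, ILC precursor was 3.45 ± 0.437 in GFP_WT, 2.48 ± 0.0151 in GFP_KO, 3.90 ± 0.434 in TOX_WT and 2.78 ± 0.0833 in TOX_KO. An exact permutation of the genotype within constructs gave an adjusted p = 0.025 for ILC precursor, ILC2, NK and ILC1 and B lineage (p = 0.005, the smallest it can give). It gave 0.04 for mast and basophil and 0.06 for myeloid, which did not pass. The genotypes did not overlap in the first 4 of these under either construct. Passed with the preset correlation alone were interferon response (7.49e-09; adjusted p = 0.0847 with an estimated correlation), integrins and homing (3.96e-09 and 0.0775), dendritic cell (0.000175 and 0.276), mitochondrial transcripts (0.000204 and 0.350), ILC3 and LTi (0.00054 and 0.109), cell cycle (0.000697 and 0.109), exhaustion-associated (0.00451 and 0.130) and erythroid and megakaryocyte (0.0233 and 0.130). The last was not past the threshold without GFP_WT replicate 2 (0.0612), GFP_KO replicate 2 (0.0563) or 3 (0.228), or TOX_WT replicate 2 (0.0584). With both GFP_KO replicates 1 and 2 left out, which leaves 1 library in that group, cell cycle (0.128), exhaustion-associated (0.287) and mitochondrial transcripts (0.0948) did not pass, with medians of 0.08 instead of 0.17, -0.61 instead of -0.82 and -0.18 instead of -0.27, and the dendritic cell median was 0.00 instead of -0.38. T lineage (0.0611), lymphoid progenitor (0.476), stroma (0.935), immediate early and heat shock (0.535), p53 targets (0.275) and circadian PAR bZIP (0.270) did not pass, and in lymphoid progenitor, stroma and circadian PAR bZIP the median, mean and test differed in sign.

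**Figure D2:**
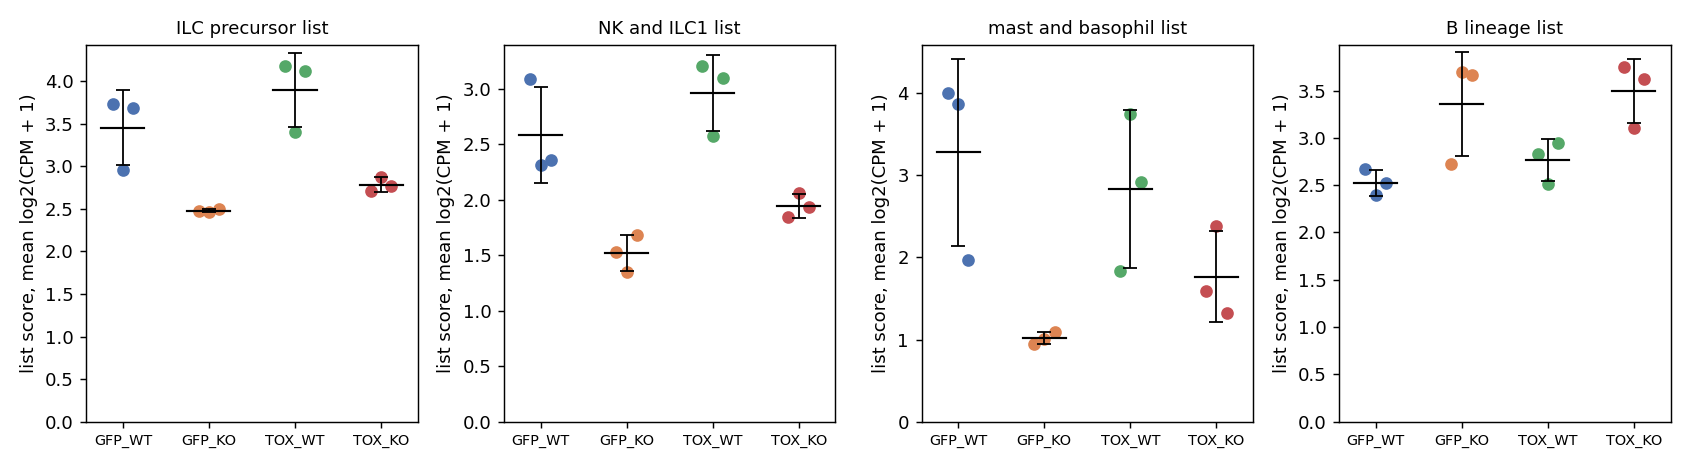
Score per library, the mean log2(CPM + 1) of the members of a list, in the 4 groups, with points for libraries, a line at the mean and bars for the SD over 3 libraries. The NK and ILC1 score is 2.59 ± 0.434 in GFP_WT against 1.52 ± 0.165 in GFP_KO, and 2.96 ± 0.341 in TOX_WT against 1.95 ± 0.109 in TOX_KO.

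The comparison of TOX_WT with GFP_WT asks what forced TOX changes when NFIL3 is present. Interferon-stimulated genes lay higher and genes of lymphoid progenitors lower with TOX, and no list passed with an estimated correlation. The interferon response list was higher in 26 of 27 members with a median of 0.91 (camera adjusted p = 5.86e-07; adjusted p = 0.325 with an estimated correlation). Ifih1, a sensor of viral RNA, had 16.6 ± 1.83 CPM with TOX and 7.38 ± 3.82 with GFP (log2 fold change 1.17 ± 0.45, not past the threshold). The lymphoid progenitor list was lower in 19 of 24 members with a median of -0.35 (camera adjusted p = 0.000416; adjusted p = 0.325 with an estimated correlation), and 0 of its members passed adjusted over the list alone. Dntt had 77.7 ± 36.4 against 208 ± 19.8 CPM (log2 fold change -1.42 ± 0.39), Cd27 50.1 ± 5.32 against 97.0 ± 15.8 and Hhex 87.6 ± 8.77 against 115 ± 4.24. The integrins and homing list was higher (0.0226; adjusted p = 0.767 with an estimated correlation), with Ccr2, a chemokine receptor, at 662 ± 49.1 against 259 ± 151 CPM (adjusted p = 0.0480 over the list alone). Erythroid and megakaryocyte was lower with a median of -1.04 (0.00940; adjusted p = 0.325 with an estimated correlation). The ILC precursor list did not pass (0.289), and Rora in it had 24.3 ± 16.9 against 1.47 ± 1.07 CPM (log2 fold change 4.05 ± 1.17, edgeR adjusted p = 0.858).

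The other lists did not pass for TOX in wild-type cells: dendritic cell (0.0697), NK and ILC1 (0.181), B lineage (0.214), myeloid (0.214), mast and basophil (0.233), mitochondrial transcripts (0.261), exhaustion-associated (0.372), ILC2 (0.421), T lineage (0.579), immediate early and heat shock (0.642), p53 targets (0.642), circadian PAR bZIP (0.687), ILC3 and LTi (0.723), and stroma and cell cycle (0.730). In ILC3 and LTi, T lineage, stroma and p53 targets the median, mean and test differed in sign. Integrins and homing was not past the threshold without GFP_WT replicate 2 (0.594) or TOX_WT replicate 1 (0.369), nor erythroid and megakaryocyte without TOX_WT replicate 3 (0.0684). With the transcript-length slope as a covariate integrins and homing did not pass (0.115), and 9 lists passed without TOX_WT replicate 2. Between single genes edgeR called 0, with a smallest adjusted p of 0.858 and 872 genes at an unadjusted p under 0.05; DESeq2 called 67 and limma-voom 0.

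The comparison of TOX_KO with GFP_KO asks what forced TOX changes without NFIL3. Myeloid, interferon-stimulated and mast cell and basophil genes lay higher with TOX, and no list passed with an estimated correlation. The myeloid list was higher in 24 of 29 members with a median of 0.95 (camera adjusted p = 5.89e-10; adjusted p = 0.0738 with an estimated correlation). Cybb, a subunit of the phagocyte oxidase, had 198 ± 61.2 CPM with TOX and 57.7 ± 26.8 with GFP (log2 fold change 1.78 ± 0.38, adjusted p = 0.0161 over the list alone). Csf1r, the receptor for macrophage colony-stimulating factor, had 197 ± 24.1 against 82.7 ± 25. Against GFP_KO replicate 3 alone, with the spread taken from the other groups, the myeloid median was 0.56 (0.0216), and mast and basophil did not pass (0.0796, median 4.00). Interferon response was higher with a median of 0.98 (7.04e-08; adjusted p = 0.317 with an estimated correlation), with Oas1a at 73.1 ± 15.8 against 27.3 ± 10.9 CPM. The mast and basophil list was higher with a median of 3.64, or 2.85 with bounds in place of fitted folds (3.7e-05; adjusted p = 0.317 with an estimated correlation). Cpa3 had 4.97 ± 4.10 against 0.360 ± 0.0911 CPM and Hdc 8.77 ± 9.58 against 0.655 ± 0.639, both past the threshold adjusted over the list alone (adjusted p = 0.0310), as was Alox5, at 1.81 ± 2.90 against 0.0245 ± 0.0254 CPM, most of it from TOX_KO replicate 2 (5.15 CPM). Without that library the log2 fold change of Hdc was 2.34 instead of 3.75. Their means in TOX_WT were 46.4 ± 27.0 CPM for Cpa3 and 20.9 ± 18.2 for Hdc.

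Integrins and homing (0.000427; adjusted p = 0.391 with an estimated correlation), stroma (0.0115 and 0.391) and ILC precursor (0.0496 and 0.391) were also higher with TOX in the knockout, and erythroid and megakaryocyte (0.0496 and 0.391) lower. In the ILC precursor list Ikzf2 had 1.84 ± 0.637 against 0.0659 ± 0.0779 CPM (adjusted p = 0.0449 over the list alone). Not past the threshold were dendritic cell (0.0678), NK and ILC1, mitochondrial transcripts and immediate early and heat shock (each 0.0747), ILC2 (0.108), p53 targets (0.206), lymphoid progenitor (0.288), circadian PAR bZIP (0.368), cell cycle (0.400), B lineage (0.466), T lineage (0.502), exhaustion-associated (0.581) and ILC3 and LTi (0.828); in ILC3 and LTi, T lineage, B lineage and cell cycle the median, mean and test differed in sign. ILC precursor was not past the threshold without GFP_WT replicate 1 (0.0681) or 2 (0.0525), GFP_KO replicate 1 (0.0702), 2 (0.0751) or 3 (0.0912), TOX_WT replicate 1 (0.0540) or 3 (0.0560), or TOX_KO replicate 2 (0.147). The same held for erythroid and megakaryocyte without GFP_WT replicate 1 (0.0581) or 2 (0.0525), GFP_KO replicate 1 (0.402) or 3 (0.0530), TOX_WT replicate 1 (0.0540) or 3 (0.0560), or TOX_KO replicate 1 (0.116), and for stroma without GFP_KO replicate 1 (0.0555) or 3 (0.116) or TOX_KO replicate 3 (0.0856). Against GFP_KO replicate 3 alone, with the spread of the other groups, ILC precursor (0.262, median 0.65 instead of 0.40), erythroid and megakaryocyte (0.686, 0.19 instead of -0.27) and integrins and homing (0.105, 0.60 instead of 0.80) did not pass. Stroma was also lost with the strict filter (0.583) and with detected genes as a covariate (0.0633). Of its 17 measured members 10 were higher and 7 lower. The list holds genes of OP9-like stromal cells and fibroblasts, and the cells were grown on OP9 stroma. Whether its counts came from stroma carried over through the sort was not tested. Between single genes edgeR called 0, with a smallest adjusted p of 0.304 and 775 genes at an unadjusted p under 0.05; DESeq2 called 133, limma-voom 0, and edgeR 17 without GFP_KO replicate 3.

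**Figure D3:**
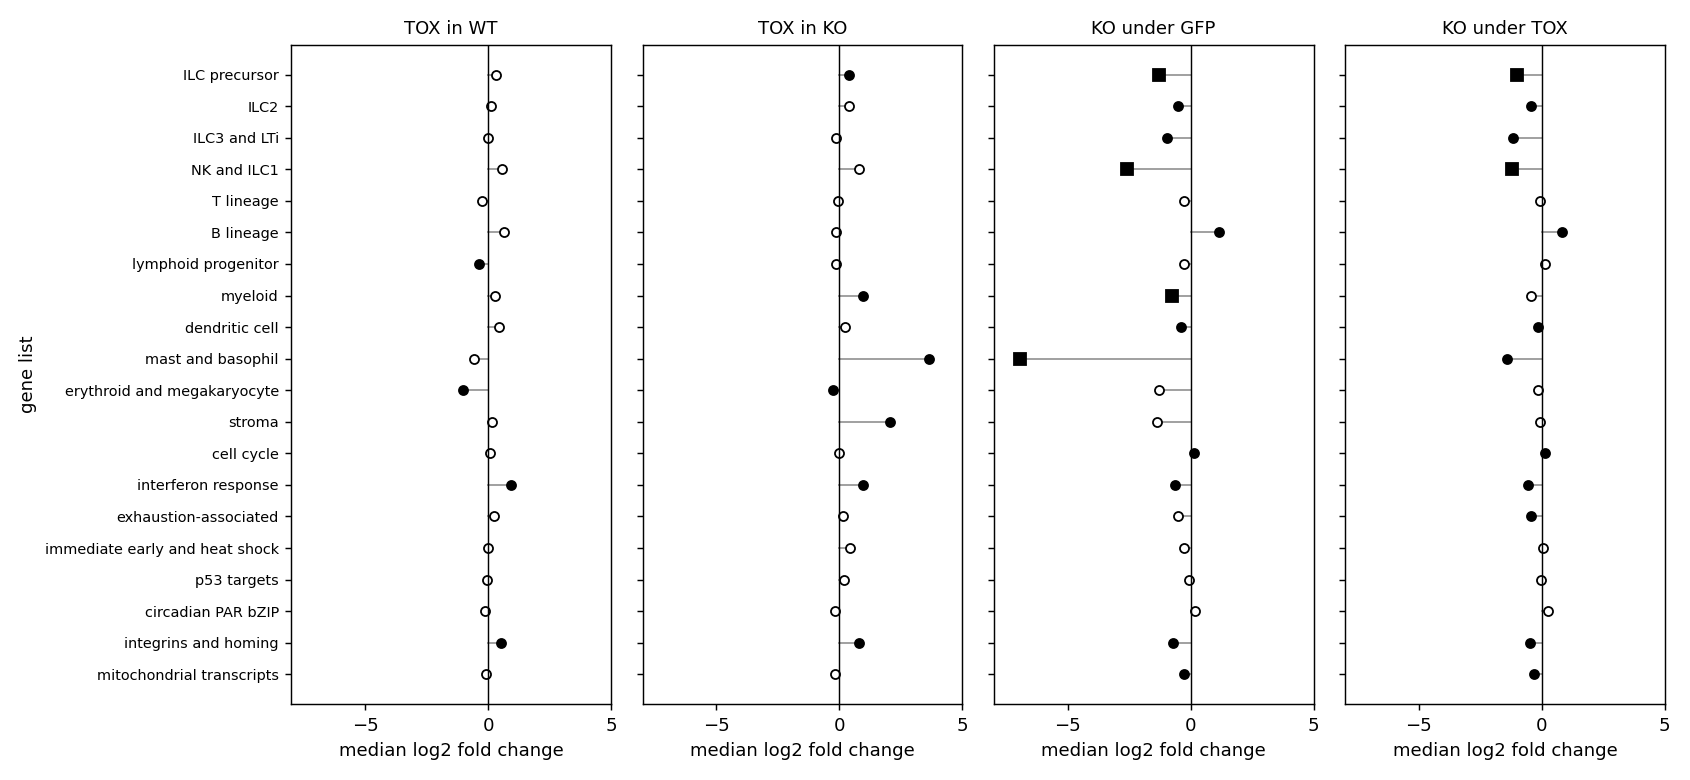
Median log2 fold change of each list in the 4 comparisons of 2 groups; open circles did not pass the camera threshold, filled circles passed with the preset correlation and filled squares also with an estimated one. ILC precursor is at -1.28 and -0.99 and NK and ILC1 at -2.60 and -1.19 for the knockout under GFP and TOX, and mast and basophil is at 3.64 for TOX in the knockout.

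The interaction asks whether the effect of TOX differs between genotypes, whose mean level of Tox with the vector also differed (33.6 CPM in TOX_KO and 65.1 in TOX_WT). For the mast and basophil list the effect differed by a median of 3.72 on the log2 scale (camera adjusted p = 2.97e-05, and 0.573 with an estimated correlation). Members at 0 in a group leave this median without a bound. With TOX the list median was 3.64 in the knockout and -0.59 in wild type, where 12 of 16 members were lower and the list did not pass. Hdc (5.35 ± 1.44) and Cpa3 (5.01 ± 1.46) were among 4 members higher adjusted over the list alone. The myeloid list (median 0.58; adjusted p = 0.00269; adjusted p = 0.573 with an estimated correlation) and the stroma list (median 1.57; adjusted p = 0.0497; adjusted p = 0.857 with an estimated correlation) passed as well. The ILC precursor list did not (adjusted p = 0.874), nor did NK and ILC1 (0.902), although Ikzf2 was past the threshold adjusted over the ILC precursor list alone (6.25 ± 1.55, adjusted p = 0.0427). The other 15 lists had an adjusted p of 0.119 to 0.934, and in interferon response, exhaustion-associated, circadian PAR bZIP and mitochondrial transcripts the median, mean and test differed in sign. Between single genes edgeR called 0 with 688 at an unadjusted p under 0.05, DESeq2 91 and limma-voom 1, and edgeR 6 without GFP_KO replicate 3. Stroma was not past the threshold without GFP_WT replicate 2 (0.988), GFP_KO replicate 3 (0.242) or TOX_KO replicate 3 (0.488), and 5 lists passed without GFP_KO replicate 1. With GFP_KO replicate 3 as the 1 library of its group, and the spread of the other groups, the myeloid list (0.220, median 0.06) and the mast and basophil list (0.0610, median 4.75) did not pass.

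Averaged over both genotypes, edgeR called 0 genes for TOX, with a smallest adjusted p of 0.273 and 1057 genes at an unadjusted p under 0.05; DESeq2 called 146 and limma-voom 1, and edgeR 4 without GFP_WT replicate 3 and 13 without GFP_KO replicate 3. By camera 10 lists passed, none with an estimated correlation and none by the exact permutation of the score per library. Higher were interferon response (3.28e-12; adjusted p = 0.128 with an estimated correlation), myeloid (3.01e-07 and 0.128), integrins and homing (6.97e-05 and 0.292), dendritic cell (0.0105 and 0.556), ILC precursor (0.0195 and 0.331), NK and ILC1 (0.0248 and 0.298) and mast and basophil (0.0252 and 0.442). Lower were erythroid and megakaryocyte (0.00114; adjusted p = 0.128 with an estimated correlation), lymphoid progenitor (0.00142 and 0.292) and mitochondrial transcripts (0.0359 and 0.657). Adjusted over the list alone, 3 myeloid members, 2 of interferon response and 2 of integrins and homing were higher, and 3 of lymphoid progenitor lower and 1 higher. The 10 lists that did not pass had an adjusted p of 0.0504 to 0.677, and in ILC3 and LTi, T lineage and cell cycle the median, mean and test differed in sign.

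Single libraries decided several of these averaged TOX calls. Without TOX_WT replicate 1, 6 lists passed: ILC precursor (0.0703), NK and ILC1 (0.0659), dendritic cell (0.0521) and mitochondrial transcripts (0.176) did not. ILC precursor also missed the threshold without GFP_WT replicate 2 (0.113) or TOX_WT replicate 3 (0.0601), NK and ILC1 without GFP_WT replicate 3 (0.140), and lymphoid progenitor without GFP_KO replicate 1 (0.0717). Dendritic cell missed it without GFP_WT replicate 2 (0.113), GFP_KO replicate 2 (0.0842) or TOX_WT replicate 3 (0.134). Mast and basophil missed it without GFP_WT replicate 3 (0.204), GFP_KO replicate 1 (0.0717) or 3 (0.0570), TOX_WT replicate 2 (0.150) or TOX_KO replicate 2 (0.246). Mitochondrial transcripts missed it without GFP_WT replicate 1 (0.555) or 2 (0.113), GFP_KO replicate 2 (0.0572) or 3 (0.203), TOX_WT replicate 2 (0.128), or TOX_KO replicate 1 (0.107) or 3 (0.0642). With both GFP_KO replicates 1 and 2 left out, which leaves 1 library in that group, 4 lists passed. Of those that did not, ILC precursor (0.104, median 0.52 instead of 0.45), NK and ILC1 (0.329, 0.65 in both), mast and basophil (0.432, 1.59 instead of 1.17) and erythroid and megakaryocyte (0.0693, -0.50 instead of -0.56) had medians of about the same size or larger. Dendritic cell (0.417, 0.26 instead of 0.41) and lymphoid progenitor (0.611, -0.01 instead of -0.25) had smaller ones.

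The responses to TOX in the 2 genotypes share no library and were compared across genes, which are not independent replicates. Their log2 fold changes had a Spearman rho of 0.0767 (jackknife SE 0.0339, Pearson 0.0323) over 15114 genes, and 0.152 over the 9046 genes with at least 5 CPM on average. At an unadjusted p under 0.05, 52 genes were higher in both against 17.8 for independent lists, and 17 were lower in both against 4.93. The knockout responses under GFP and TOX had a Spearman rho of 0.101 (jackknife SE 0.0704, Pearson 0.0944), and 0.155 over the same 9046 genes. With GFP_KO replicate 3 as the 1 library of its group it was -0.00430. At an unadjusted p under 0.05, 80 genes were lower in both against 9.94 for independent lists and 47 higher in both against 11.1. For TOX and for the knockout alike, the 2 tests of a gene drew on one estimate of its spread from all 12 libraries. The lists are therefore not independent even with no shared response, and these counts do not measure one. Genes that moved in opposite directions were not counted. Nfil3 was the 1 gene called in both.

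In the authors' deposited statistics, which cover 10219 genes, 0 had an adjusted p under 0.05 for TOX in wild type or in the knockout, with smallest values of 0.550 and 0.398; 674 and 435 had an unadjusted p under 0.05. Their log2 fold changes correlated with the edgeR values at a Pearson r of 0.835 and 0.803 over 9627 matched genes. The authors' log2 fold change of Tox was 2.69 in wild type (authors' adjusted p = 0.651) and 1.35 in the knockout (authors' adjusted p = 0.9999). These values are given beside normalized values, and the input of the authors' test is not stated.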

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

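The tests of detected genes, of a varying share of cells and of transcript length were chosen only after the results they weigh had been seen, and after its values were known the bounds of the cell-share test were moved from the median to the quartiles of the 20 lists, and its contrast was changed for mast and basophil to TOX in the knockout. The tests of other splits and of GC content were set beforehand.

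The response to TOX differed between genotypes in 3 lists by the interaction test with the preset correlation. The myeloid list passed at an adjusted p of 0.00269, with 0.000301 to 0.573 over its alternatives other than leaving out 1 library. Its median was 0.0564 instead of 0.58 without GFP_KO replicates 1 and 2, a fit that rests on 1 GFP_KO library. The stroma list passed at 0.0497, with a highest value of 0.857 over the same alternatives. It holds genes of cells like the OP9 stroma of the culture, and carry-over of stroma was not tested. The mast and basophil list passed at 2.97e-05, with 6.82e-07 to 0.573 over the same alternatives.

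The ILC precursor and NK and ILC1 lists lay lower in the knockout under both constructs, from cells for which no sort removes ILCs. Fewer detected genes in knockout libraries is argued against: the list medians were -0.99 and -1.19 between TOX_KO and TOX_WT, where the knockout libraries had more genes with a count (a mean of 16986 against 16182). A share of ILC-type cells that varies between cultures cannot be told apart from a change within cells. The estimated correlations within groups, 0.132 and 0.0844, lie between the quartiles of the 20 lists (7 and 12 lists are higher). They cannot decide it, because a share that differs between genotypes need not vary between replicates of a group. Id2 and Nkg7, at 107 and 122 CPM in GFP_WT, were the most abundant of the members lower adjusted over the list alone. The lists share 1 gene with each other, and ILC precursor shares 5 with ILC2. Each also shares 1 gene with the mast and basophil list, Il1rl1 for ILC precursor and Gzmb for NK and ILC1. The loss of NFIL3, which the design sets, may act on the number of such cells or on the genes in each cell, and this was not tested. The labels write the Tcf7 reporter genotype differently for the knockout. A difference in reporter alleles, if there is one, cannot be told apart from the loss of NFIL3.

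The mast and basophil list was higher with TOX in the knockout, although TOX_KO stayed below TOX_WT in Cpa3 (4.97 against 46.4 CPM). Over the alternatives other than leaving out 1 library, the adjusted p of this list ran from 3.25e-07 to 0.317. Fewer detected genes in GFP_KO replicates 1 and 2 is argued against as the whole cause, but only weakly. The list stayed higher with detected genes as a covariate (camera adjusted p = 3.25e-07), a fit run with the preset correlation only. Without the covariate the list did not pass with an estimated correlation (camera adjusted p = 0.317). Leaving those libraries out gave an adjusted p of 0.0796 with a median of 4.00 instead of 3.64, but this sets TOX_KO against 1 GFP_KO library with the spread of the other groups, and decides nothing about the cause. A share of mast or basophil cells that varies between cultures of one group stays open beside an effect of TOX. It met its test, with an estimated correlation of 0.223 between members against an upper quartile of 0.205 (4 lists are higher). That outcome depends on the contrast, which was changed after its values were known. In the averaged knockout effect, used for the ILC lists, the correlation was 0.211 and not above the upper quartile, so the test cannot decide this. The estimated correlation is an average over the members and groups, and 2 members did not move together in TOX_KO. There Hdc had 1.97, 19.7 and 4.61 CPM and Cpa3 7.94, 6.68 and 0.294. The list shares 1 gene each with ILC precursor, ILC2 and NK and ILC1, and whether the Mac1-negative sort removes such cells was not tested.

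Another split of the 6 GFP libraries called far more genes than the genotype did, which points to a structure of the samples. With GFP_WT replicate 3 and GFP_KO replicates 1 and 2 on one side, edgeR called 1103 genes, 607 higher and 496 lower, with median transcript lengths of 1672 and 772.5 nt; of 81 cytosolic ribosomal protein genes 58 were lower and 0 higher. A bias by transcript length that differs between libraries may be part of it and cannot be told apart from other causes. The slopes against transcript length were 0.118, 0.0615 and 0.0393 in the libraries of this side and -0.0743, -0.177 and -0.0953 in the others. Across 14705 genes the Spearman rho was 0.187. Each length was the median over all annotated transcripts of a gene, which need not be the length expressed, so this rho does not bound the part of length. A steady rise or fall with GC content is argued against, with a rho of 0.00706. GC content was also the median over all annotated transcripts of a gene, and a bias that does not rise or fall steadily was not tested. DESeq2 called as many genes in other splits: up to 2218 against 200 for the genotype under GFP and up to 177 against 67 for TOX in wild type, so its larger counts do not set the real groups apart; no biological explanation was tested.

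Chance was weighed by refitting other splits of the same libraries. For each comparison of 3 against 3 the 10 splits are too few for a share under 0.05. The gene counts there were 0 for TOX in wild type (highest other 0; 10 splits gave as many), 0 for TOX in the knockout (highest other 1; 10 splits), 1 for the knockout under GFP (highest other 1103; 2 splits) and 1 under TOX (highest other 0; 1 split). The list counts were 4 (highest other 9; 6 splits), 7 (8; 2 splits), 12 (8; 1 split) and 12 (9; 1 split) in the same order. Over 100 splits of the 12 libraries, the real one included, few gave as many passing lists. As many passed in 3 splits for the averaged TOX effect (10 lists, highest other 13) and in 3 for the averaged knockout effect (14 lists, highest other 15). Both shares are under 0.05 but are not adjusted over the counts weighed here, so chance is less likely without being excluded. Nor do these shares bear on single lists, of which the exact permutation of scores left 0 for averaged TOX. Nor was chance excluded for the 12 genes of the averaged knockout effect (10 splits, highest other 229) or the 3 lists of the interaction (75 splits, highest other 13). A count of 0 cannot be weighed this way, because every split gives at least 0. This holds for the 0 genes of the averaged TOX effect (100 splits, highest other 0) and of the interaction (100 splits, highest other 641). The splits with 229 and 641 genes had GFP_WT replicate 3 and GFP_KO replicates 1 and 2 on one side, which points to a structure of the samples. The same held for every other split of the averaged knockout or the interaction that called a gene, apart from the real knockout split. The share of 10 splits for the 12 genes therefore carries that structure and cannot decide on chance.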

How the results depend on the processing

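Chosen after the data were seen were the fits without GFP_KO replicates 1 and 2 (the 2 libraries with the fewest detected genes, so that 1 is left in the group and the others give the spread), with detected genes or the transcript-length slope as a covariate, and the score per library. The tool moved the gene counts most, and the cause was not tested: DESeq2 called 67 genes for TOX in wild type, 133 for TOX in the knockout, 200 and 88 for the knockout under GFP and TOX, 91 for the interaction, 146 for averaged TOX and 249 for the averaged knockout. Limma-voom called 0 and 0 for the knockout under GFP and TOX, 1 for the interaction, 1 for averaged TOX and 7 for the averaged knockout; with sample weights it called 0 under GFP and 12 under TOX. The knockout under GFP gave 6 genes without a filter, 5 with the strict filter and 0 when fitted on the groups compared only (fewer libraries for the spread), and under TOX 2 without GFP_KO replicates 1 and 2. The averaged knockout gave 22 without a filter and 22 with the strict one, 2 without GFP_KO replicates 1 and 2, 2 with detected genes and 1 with the length slope as a covariate. With an estimated correlation, which lowers the weight of lists whose members move together, 0, 0, 4 and 2 lists passed for TOX in wild type, TOX in the knockout and the knockout under GFP and TOX, 0 for the interaction, 0 for averaged TOX and 6 for the averaged knockout; with fry, which compares no list with other genes, these were 0, 0, 6, 1, 0, 0 and 6. The score per library left 0 lists for averaged TOX and 5 for the averaged knockout. For TOX in the knockout 4 lists passed with the strict filter, and 4 for it and for averaged TOX without GFP_KO replicates 1 and 2. The Spearman rho between the TOX responses was 0.138 with the strict filter, 0.0270 without GFP_KO replicates 1 and 2 and 0.137 with the length slope, and that between the knockout responses was -0.00430 without these replicates; the cause was not tested. Tox passed by DESeq2 for averaged TOX (log2 fold change 1.71, adjusted p = 0.0206). Nfil3 kept its fold but not its call under GFP by limma-voom (-5.41), by limma-voom with sample weights (-5.24) and on the groups compared only (-5.41), and under TOX by limma-voom (-4.64). The mitochondrial list under GFP reversed in the direction of its test without GFP_KO replicates 1 and 2 (adjusted p = 0.976). This fit rests on 1 GFP_KO library, and the list median stayed negative, at -0.02 instead of -0.25, with 6 members higher and 7 lower. The adjusted p of this list ran from 0.0126 to 0.976 over the alternatives other than leaving out 1 library. Leaving out 1 library gave 1.16e-06 (GFP_WT replicate 3) to 0.833 (GFP_WT replicate 1), and the cause was not tested. Leaving out each library in turn gave 0 genes for TOX in wild type, 0 to 17 for TOX in the knockout, 1 to 36 for the knockout under GFP and 1 to 2 under TOX, 0 to 6 for the interaction, 0 to 13 for averaged TOX and 1 to 36 for the averaged knockout. Lists ran from 3 to 9, 5 to 9, 9 to 13, 10 to 14, 2 to 5, 6 to 10 and 13 to 15 in the same order. The log2 fold change of Tox ran from 1.64 to 3.55 in wild type, 1.03 to 1.79 in the knockout and 1.47 to 2.42 averaged, and that of Nfil3 from -5.58 to -5.14 under GFP, -4.77 to -4.44 under TOX and -5.12 to -4.90 averaged. With the replicate number as a block, the averaged knockout gave 4 genes; same-numbered libraries correlated at -0.0747 to 0.0779 in their deviations, 0 of 18 pairs above 0.1, and 5 of 12 libraries correlated best with their own number, so the numbers are not read as pairs. Among single lists and named genes, 2265 values under an alternative kept their direction and side of the threshold, 381 no longer passed, 55 newly passed and 1 reversed; the block ended the call of 3 lists (ILC precursor and TOX in the knockout, 0.0518; stroma and interaction, 0.105; erythroid and megakaryocyte and averaged knockout, 0.0584). Beyond the lists named above, single calls also ended as follows. For TOX in wild type, integrins and homing with the length slope (0.115). For TOX in the knockout, stroma with the strict filter (0.583) and detected genes (0.0633), ILC precursor with RLE (0.05001), the strict filter (0.133) and the length slope (0.142), and erythroid and megakaryocyte with RLE (0.0602), the strict filter (0.299), detected genes (0.461) and the length slope (0.113). For the knockout, mitochondrial transcripts under GFP (0.158), cell cycle under TOX (0.0880) and averaged erythroid and megakaryocyte (0.0595), each with the length slope. For the interaction, stroma with the strict filter (0.225), detected genes (0.102) and the length slope (0.258). For averaged TOX, ILC precursor (0.165) and mitochondrial transcripts (0.618) with the length slope, the latter also with the strict filter (0.0522), and lymphoid progenitor (0.154) and dendritic cell (0.0789) with detected genes. Depth limits only genes near the floor of 0.0678 to 0.0759 CPM.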

Other observations

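The mean level of Tox was 65.1 ± 15.0 CPM in TOX_WT and 33.6 ± 5.99 in TOX_KO, every TOX_WT library above every TOX_KO library (log2 fold change of the knockout -0.96 ± 0.68, not past the threshold by edgeR). Counts of the vector and of the cell's own gene cannot be separated in it, so the dose of forced TOX in the genotypes is not known from these values. The slope of each library's log2 CPM, as a deviation from the mean of the libraries, against log2 transcript length over 9000 genes was 0.118 in GFP_WT replicate 3, 0.0615 and 0.0393 in GFP_KO replicates 1 and 2, and -0.0743, -0.177 and -0.0953 in GFP_WT replicates 1 and 2 and GFP_KO replicate 3. In the 6 TOX libraries it lay between -0.0281 and 0.0461.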
